A study of Caenorhabditis elegans with 24 samples.

How the data were processed

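Small RNA was sequenced from whole Caenorhabditis elegans animals of 6 alg-1 genotypes: wild type (WT), 4 alleles modelled on human AGO1 changes found in neurodevelopmental disorders (NDD; F180del, G199S, V254I and H751L) and an alg-1 null. ALG-1 is one of the Argonaute proteins that hold microRNAs (miRNAs). From each genotype 2 libraries came from total small RNA of the lysate and 2 from small RNA co-precipitated with ALG-1 (IP), 24 libraries in 12 groups. Animals were synchronised by hatching embryos without food and were harvested after 45 h of feeding at 20 °C, with the stage examined by microscopy, per the labels' protocols. Labels number the libraries 1 and 2 in every group but do not say whether these came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

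The deposited count table holds whole reads per mature miRNA and precursor for each library. FastQC 0.11.8, cutadapt, Bowtie 1.2.2 and DESeq2 are named, without their roles, per the submitters' processing notes. The genome build, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. A second deposited sheet repeated these counts in 100.0% of cells, and the authors' deposited RPM sheet (reads per 1000000 miRNA reads) equalled the counts divided by the library total within 1 RPM in 100.0% of cells. A further sheet with 48 per-sample columns whose names match no label was not used. The table has 450 rows for 253 precursors and 437 mature names. Of the names, 10 are listed for more than one precursor, and the row with the highest total was kept, which removed 13 rows. Identical or near-identical mature miRNAs can share reads, so single members of such families (miR-44-3p and miR-45-3p, the miR-35 family, miR-52-5p and miR-53-5p) are uncertain.

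Library totals ran from 3940626 to 13835895 miRNA reads. A count of 0 allows up to 3 reads, which is 0.217 to 0.761 RPM per library. Folds against a group at 0 were computed against 3 reads over the group. Binomial intervals (exact, 95%) and these floors cover counting error only. The reason is that no count of molecular identifiers is stated and PCR reads are not independent molecules. Reads assigned to miRNAs give no measure of the alg-1 transcript or of the yield of each precipitation, so the genotype could not be checked from the target gene, and all levels are relative within a library.

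Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr on group, TMM factors, and the quasi-likelihood F-test on group means. One fit held the 12 total libraries (303 miRNAs tested), one the 12 IP libraries (269) and one all 24 (315), so that the spread was shared over genotypes. Adjusted p-values are Benjamini-Hochberg over all miRNAs tested in a comparison, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Comparisons were each genotype against WT in total and in IP, IP against total in WT, the IP to total ratio of each genotype against that of WT (an interaction), each NDD allele against null in total, and an F-test among the 4 NDD alleles in each fraction. Against library totals, TMM lowered the log2 changes of all miRNAs by 0.51 in F180del total, 0.67 in F180del IP, 0.20 in G199S total, 0.30 in G199S IP, 0.19 in V254I IP and 0.13 in null total. It raised them in H751L total, H751L IP and null IP, where the shifts with library totals were -0.16, -0.24 and -0.25.

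Hairpins with both arms named numbered 189. The arm with more reads over the 12 total libraries was called the guide and the other the passenger. Passenger to guide ratios were tested per hairpin with limma 3.58.1 (trend) on log2 of the 2 counts, each plus 0.5, for hairpins with a mean passenger count of at least 10 (99 in total, 83 in IP). The passenger share is the sum of passenger reads over all miRNA reads of a library. Sets of miRNAs were tested with camera (preset correlation, then an estimated one) and fry: 15 lists of seed families, tissue-restricted, stress and lifespan, intended mirtron and RDE-1 associated miRNAs, and the passenger strands as a set. Fry tested whether a set moved one way and passed in 15 of the list comparisons, camera in 14. Fisher's exact test compared passenger shares among called and other miRNAs. Log2 changes of NDD alleles were correlated with those of null across miRNAs, which are not independent replicates, beside 100 simulated draws of unchanged groups against the same WT libraries. Overlaps of calls were set beside the overlap, in those draws, of as many top-ranked miRNAs by p in the same direction, a comparison chosen after the overlaps were seen. With 2 libraries against 2, a two-sided exact permutation test of one value cannot go below 0.333.

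Design, lists, alternatives and the naming rule were fixed before the data were examined. Named were, per comparison, up to 8 higher and 8 lower miRNAs by size of log2 change among those past the threshold, with non-overlapping libraries and a mean of at least 10 RPM, up to 5 hairpins per direction by the same rule, and any member of the lists. Alternatives were RLE size factors, library totals, no filter, DESeq2 1.42.0, a replicate block, all precursor rows, only the compared groups in the fit, and each library left out. Other pseudocounts and count minimums were tried for ratios.

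The tests were checked on simulated counts drawn from the real means, library sizes and dispersions, with 100 miRNAs changed 4-fold and 100 changed 16-fold. In null against WT in total, 37% and 81% of these were called, with those that the filter removed counted as missed. The filter kept 264 of 303 simulated miRNAs, of which 89 were unchanged, and 3.37% of the 89 were called. In IP the shares were 56% and 80%, and 1.64% of the 61 unchanged among 239 kept of 269. Of 30 hairpins with a ratio raised 8-fold in G199S, 33.3% were called among 99 in total and 33.3% among 83 in IP. Precursor positions were taken by name from the WBcel235 annotation (250 of 253 matched). Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.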

Results

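The libraries profiled miRNA levels in lysate (total) and miRNA association with ALG-1 (IP) in animals carrying 1 of 4 NDD alleles of alg-1, an alg-1 null or no alg-1 mutation, with 2 libraries per genotype and fraction. Totals lay between 4927806 miRNA reads (WT total, library 1) and 12654183 in total RNA, and between 3940626 (F180del, library 1) and 13835895 in IP. Between 257 and 351 miRNAs had reads in total libraries and between 269 and 327 in IP libraries of alleles other than null. The null IP libraries had reads for 153 and 232 miRNAs. In WT total RNA miR-1-3p, the muscle miRNA, led both libraries, with 24.3% and 27.8% of reads, and in the WT IP miR-228-5p, found in glia, led with 13.6% and 13.2%.

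The first question was how each allele changed miRNA levels in total RNA. In F180del 34 of 303 miRNAs rose and 13 fell against WT. miR-85-3p and miR-246-3p, both on the stress and lifespan list, rose by 7.01 ± 1.55 and 3.20 ± 0.58 on the log2 scale (SE, n = 2 per group; edgeR adjusted p = 0.0113 and 0.00481). miR-85-3p was at 300 and 4947 RPM in the 2 F180del libraries, and its log2 change was 8.74 without F180del library 1 and 4.57 without library 2. miR-246-3p went from 336 ± 98.7 RPM in WT to 4226 ± 990 RPM (SD, n = 2). The let-7 relative miR-795-5p rose from 10.4 ± 6.38 to 201 ± 17.3 RPM, and among miRNAs that fell were miR-234-3p, miR-355-5p, miR-229-3p, miR-90-3p (also on the stress and lifespan list) and miR-42-3p, the last by 2.25 ± 0.53 on the log2 scale. Among the miRNAs that rose were miR-236-5p (5.91 ± 0.88), miR-44-5p (3.82 ± 0.70) and miR-79-5p (3.71 ± 0.72), the minor arms of their hairpins. Of the miR-35 family, made in embryos and germline, miR-39-3p rose and miR-42-3p fell, and 6 of 8 did not pass (3 higher and 1 lower adjusted over the list alone). The miR-44 family passed camera as lower (adjusted p = 0.0199), with 1 of 4 members called, 3 adjusted over the list alone, and adjusted p = 0.750 with an estimated correlation. Its members miR-44-3p and miR-45-3p were nearly equal in every library (11446 and 11448 RPM in F180del total library 1). The list thus counts nearly the same values under both names. The count of 47 rested on the WT libraries: without WT library 1 it was 1, and without WT library 2 it was 16. It was 25 with only the compared groups in the fit and 80 with DESeq2, and the split was 47 higher and 3 lower with library totals.

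In G199S 33 miRNAs rose and 3 fell in total RNA. The miR-35 family stood out: 6 of 8 members rose (7 adjusted over the list alone), with a median log2 change of 4.16. miR-35-3p went from 1825 ± 641 RPM in WT to 45262 ± 8056 RPM (4.44 ± 0.58, adjusted p = 0.000108), miR-40-3p from 1696 ± 654 to 24056 ± 10112 RPM (3.62 ± 0.69), and miR-39-3p from 409 ± 86.1 to 14108 ± 2627 RPM (4.91 ± 0.66). miR-41-3p did not pass (3.08 ± 1.01, adjusted p = 0.0566), nor did miR-42-3p (-0.36 ± 0.51, adjusted p = 0.688), at 12906 ± 1099 RPM in WT and 11467 ± 976 RPM in G199S. The passengers miR-39-5p and miR-41-5p rose by 10.03 ± 1.29 and 5.69 ± 0.77. The family passed camera (adjusted p = 7.15e-06), with adjusted p = 0.215 with an estimated correlation. In the WBcel235 annotation mir-35 to mir-41 lie together on chromosome II, from 11537608 to 11538404, within an intron of Y62F5A.9 on the opposite strand. mir-42 lies apart on chromosome II at 11889811 to 11889905, outside protein-coding genes. The 6 members that rose all lie in the mir-35 to mir-41 cluster, so their rises may not be independent. miR-85-3p rose by 7.47 ± 1.59 and miR-246-3p by 2.48 ± 0.56. The 3 miRNAs that fell were lin-4-5p, which times larval development (from 7049 ± 3952 to 1692 ± 305 RPM), miR-47-3p and miR-8200-3p, from 56.9 ± 6.26 to 0.112 ± 0.0147 RPM. The miR-44 family passed camera as lower with no member called (3 adjusted over the list alone; adjusted p = 0.0271, and adjusted p = 0.833 with an estimated correlation). Here too the nearly equal miR-44-3p and miR-45-3p entered the list under both names. The count of 36 was 18 to 21 without either G199S library, 12 without WT library 1, 20 without WT library 2, 82 with only the compared groups, 74 with DESeq2 and 62 without the filter. The calls split 30 higher to 10 lower with RLE factors. miR-85-3p missed the threshold without either WT library, in G199S and in F180del.

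**Figure D1:**
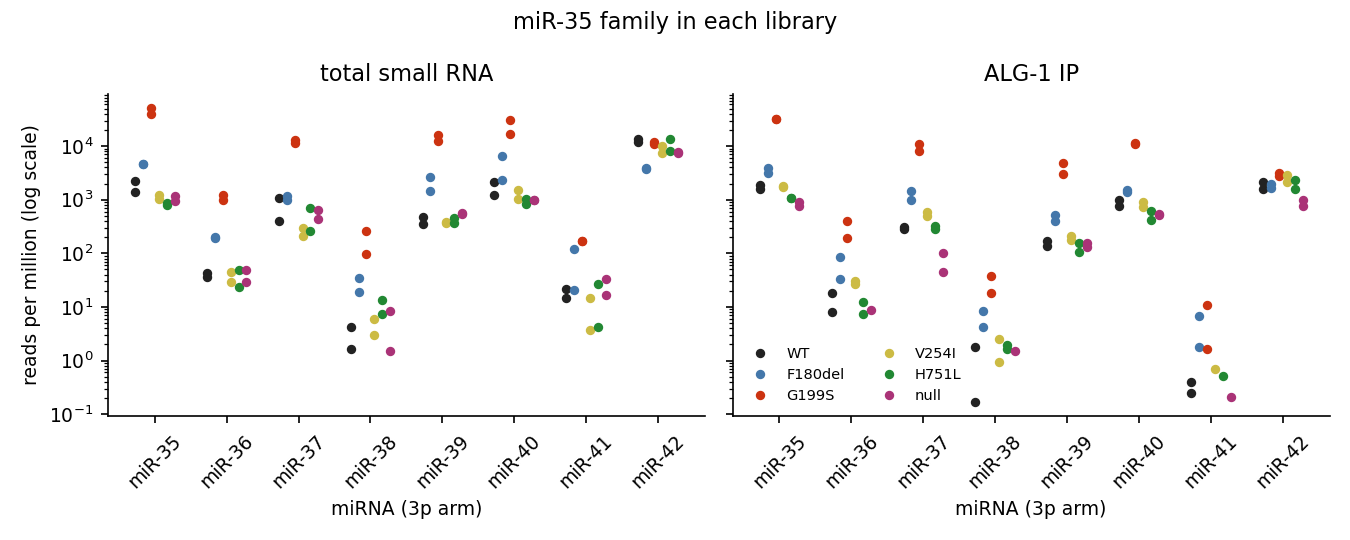
RPM (log axis) of the 8 members of the miR-35 family in each of the 2 libraries per genotype, in total RNA (left) and IP (right); values of 0 are not drawn. G199S (red) reached 45262 RPM of miR-35-3p in total RNA on average against 1825 in WT, while miR-42-3p lay at 11467 and 12906 RPM.

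Few miRNAs were called in total RNA in V254I and H751L, which does not show that few changed. In V254I no miRNA passed by edgeR or DESeq2, with 16 of 303 at an unadjusted p under 0.05, and 1 passed without the filter on low counts. In H751L 5 miRNAs rose and 1 fell. The 5 were passengers, among them let-7-3p (from 33.4 ± 11.9 to 346 ± 251 RPM), miR-235-5p, miR-240-5p and miR-51-3p (3.02 ± 0.68), and the lower one was miR-8200-3p (-3.50 ± 0.68, adjusted p = 0.0259). The passenger set passed camera in H751L (adjusted p = 0.0288, and adjusted p = 0.737 with an estimated correlation; 5 of 115 rose and 12 adjusted over the list alone). Leaving out any 1 library of H751L or WT left at most 1 call, 1 was left with all precursor rows and 0 with only the compared groups. DESeq2 called 19, and 14 were called without the filter.

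The null had 23 higher and 13 lower miRNAs in total RNA. Those that rose included the passengers lin-4-3p (5.70 ± 1.42), miR-79-5p (5.16 ± 0.77), miR-82-5p, miR-77-5p, miR-1-5p and let-7-3p. Among those that fell were miR-799 (from 60.3 ± 11.5 to 1.84 ± 0.64 RPM), miR-788-5p, miR-785-3p and members of the list set up beforehand as mirtrons. In the WBcel235 annotation mir-62, mir-1019 and mir-1020 of this list lie in introns of protein-coding genes, while mir-255 and mir-1018 lie outside protein-coding genes, so the list is not a set of mirtrons by position. Of 5 members tested, 3 fell (5 adjusted over the list alone): miR-255-3p from 109 ± 2.75 to 10.1 ± 1.87 RPM (-3.57 ± 0.66, adjusted p = 0.00432), miR-1020-3p by 2.39 ± 0.67 in log2 size and miR-1018. The list passed camera (adjusted p = 0.000136), with adjusted p = 0.131 with an estimated correlation. let-7-5p, the late larval timing miRNA, was at 19773 and 4166 RPM in the 2 null libraries and miR-124-3p, a neuronal miRNA, at 406 ± 437 RPM, against 6707 ± 1542 and 200 ± 1.23 RPM in WT; neither passed. The count of 36 was 18 without either null library, 3 without WT library 1, 11 without WT library 2, 11 with only the compared groups and 67 with DESeq2. The excess of higher calls did not hold throughout: the split was 10 higher to 14 lower with all precursor rows, 0 to 3 without WT library 1 and 9 to 9 without null library 2.

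**Figure D2:**
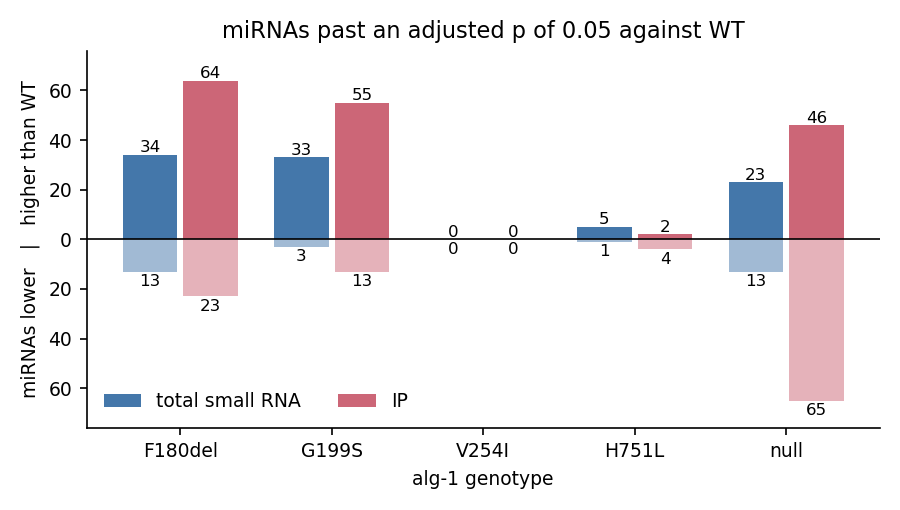
Number of miRNAs past an adjusted p of 0.05 against WT (edgeR), higher above and lower below the line, for each genotype in total RNA (blue) and IP (red). F180del had 64 higher and 23 lower in IP, the null 46 higher and 65 lower, and V254I 0.

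The IP libraries addressed which miRNAs were recovered with each ALG-1 protein. No background was subtracted, and the yield of each precipitation is not known. The null IP, without ALG-1, kept much of the WT pattern of IP to total ratios (r = 0.854 over 108 guides). Changes in binding to ALG-1 were thus not separated from a changed share of background. In the F180del IP 64 of 269 miRNAs rose and 23 fell. The miRNAs that rose were mostly passengers: miR-87-5p rose from 0.167 ± 0.122 to 70.0 ± 22.6 RPM, miR-72-3p from 15.1 ± 1.08 to 2458 ± 400 RPM (6.67 ± 0.54, adjusted p = 2.71e-05) and miR-77-5p from 11.3 ± 1.88 to 1443 ± 266 RPM. The guides miR-85-3p, miR-246-3p and miR-79-3p rose by 4.84 ± 0.50, 3.58 ± 0.35 and 3.25 ± 0.54. Among the 23 that fell, 3 of 9 tissue-restricted miRNAs were miR-228-5p of glia (from 134153 ± 2507 to 64454 ± 4487 RPM), miR-1-3p of muscle (-1.30 ± 0.40) and miR-244-5p, and 3 of 6 of the miR-51 family were miR-51-5p, miR-55-3p and miR-56-3p (-1.37 ± 0.29); each count was also 3 adjusted over the list alone, and neither list passed camera. The count of 87 was 48 without WT library 1, 39 without WT library 2, 56 without F180del library 2 and 138 with only the compared groups. With library totals 85 were higher and 8 lower.

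In the G199S IP 55 miRNAs rose and 13 fell. The miR-35 family was raised as in total RNA, with 5 of 8 members called (7 adjusted over the list alone) and a median log2 change of 4.02: miR-35-3p went from 1731 ± 188 to 31832 ± 221 RPM (3.90 ± 0.26, adjusted p = 3.9e-06) and miR-37-3p from 294 ± 20.2 to 9479 ± 1857 RPM. miR-42-3p was at 1827 ± 388 RPM in WT and 2957 ± 348 RPM in G199S and did not pass. The family had camera adjusted p = 4.97e-05, and adjusted p = 0.339 with an estimated correlation. Of the let-7 family 3 of 7 fell (3 adjusted over the list alone): let-7-5p from 13840 ± 1218 to 7541 ± 305 RPM (-1.17 ± 0.21), miR-84-5p and miR-241-5p; the list missed camera (adjusted p = 0.0580). miR-85-3p rose by 4.26 ± 0.49 and the passengers miR-44-5p and miR-87-5p by 6.71 ± 0.58 and 7.02 ± 0.89. miR-8200-3p fell from 71.7 ± 8.93 to 0.131 ± 0.185 RPM, and miR-243-3p, which loads the Argonaute RDE-1, fell by 1.67 ± 0.42 in log2 size. The count of 68 was 35 without WT library 1 and 31 without WT library 2, and the calls split 51 higher to 22 lower with RLE factors and 61 to 5 with library totals.

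In the V254I IP no miRNA passed by edgeR or DESeq2, with 8 of 269 at an unadjusted p under 0.05. The let-7 family passed camera as lower there (adjusted p = 0.0255) with no member called (0 adjusted over the list alone), with adjusted p = 0.281 with an estimated correlation, and missed it with library totals. In the H751L IP miR-51-3p and miR-85-3p rose (4.57 ± 0.72 and 2.37 ± 0.45) and 4 miRNAs fell, among them miR-8200-3p (from 71.7 ± 8.93 to 1.21 ± 0.0253 RPM) and miR-243-3p (from 221 ± 49.5 to 43.3 ± 5.91 RPM). The 6 calls were 2 to 3 with any 1 of the H751L or WT libraries left out, and 26 with only the compared groups, 21 with DESeq2 and 13 without the filter.

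The null IP, which holds what the precipitation recovers without ALG-1, had 46 higher and 65 lower miRNAs, around a median log2 change of -0.77 over all miRNAs tested. Of the let-7 family 4 of 7 rose (4 adjusted over the list alone), let-7-5p from 13840 ± 1218 to 41663 ± 9915 RPM (1.82 ± 0.22, adjusted p = 0.000611) and miR-48-5p from 72052 ± 14564 to 139853 ± 20347 RPM. miR-71-5p, an ageing miRNA, rose to 121839 ± 40061 RPM. The miR-63/64 family fell in 5 of 5 members (5 adjusted over the list alone), miR-64-5p from 20107 ± 5038 to 3059 ± 562 RPM and miR-63-3p by 1.73 ± 0.36 in log2 size. Both lists had a camera adjusted p of 0.0439, 1 of the 2 passed with library totals, and adjusted p = 0.497 (let-7) and 0.666 (miR-63/64) with an estimated correlation. Also lower were miR-788-3p, miR-799 and miR-243-3p, 3 of 9 tissue-restricted miRNAs (0 adjusted over the list alone), miR-124-3p, miR-57-5p and miR-244-5p, and 2 of 4 on the list set up as mirtrons (3 adjusted over the list alone), miR-255-3p and miR-1020-3p. miR-8200-3p had 0 reads in both null IP libraries against 1743 in WT, at least 349-fold lower if only counting error is allowed for. Null IP library 1 also had 0 reads of miR-239a-5p, which was at 28.9 RPM in library 2. A 0 in that library may thus hide a higher level than the bound allows. The count of 111 was 168 without null library 2, 62 and 63 without WT library 1 and 2, and 18 with only the compared groups. The excess of lower calls turned with 1 library: the split was 70 higher to 25 lower without null library 1 and 49 to 119 without null library 2, and it was 15 to 3 with only the compared groups.

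**Figure D3:**
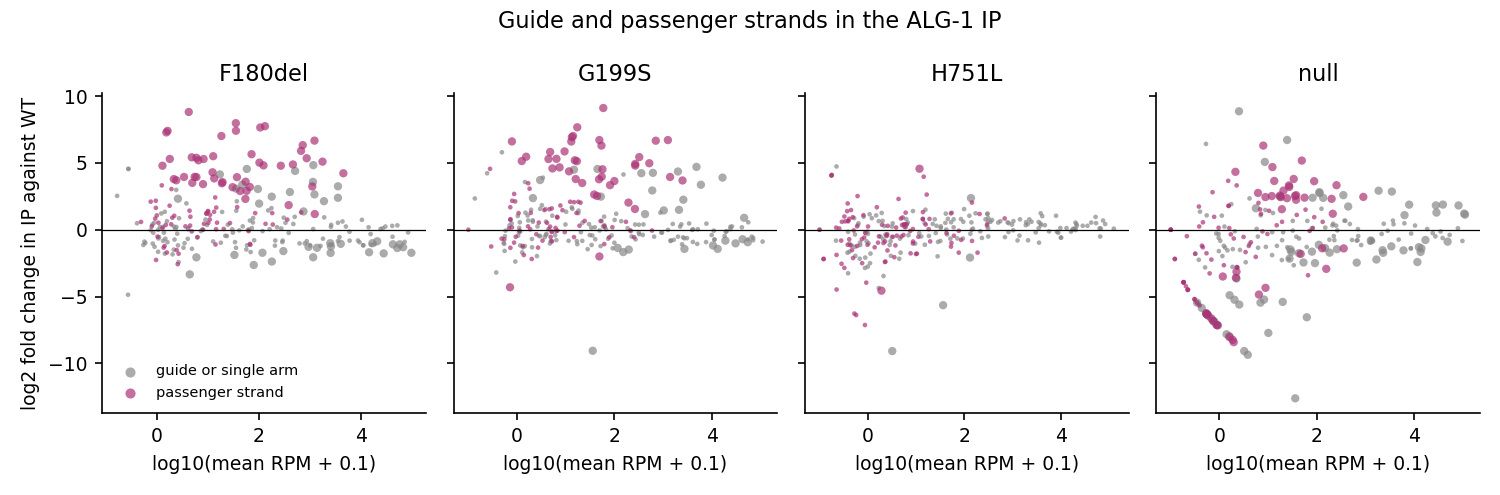
Log2 fold change in IP against WT of each of 269 miRNAs by mean abundance (log10 of RPM plus 0.1), in F180del, G199S, H751L and null; large points passed an adjusted p of 0.05 and purple points are passenger strands. Of miRNAs with both arms named, 47 of 61 higher calls in F180del and 38 of 53 in G199S were passengers.

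Passenger strands were here the arms with fewer reads over the total libraries. They made up 0.252% ± 0.0278 of reads in the WT IP (SD, n = 2), 3.07% ± 0.414 in the F180del IP and 1.83% ± 0.0995 in the G199S IP. The last 2 were 12.2 and 7.27 times the WT share. Some passengers were the major arm in the WT IP, and their reads enter these shares and folds. Among them were miR-229-5p (492 and 594 RPM, miR-229-3p 66.9 ± 12.1) and miR-788-5p (279 ± 107 RPM, miR-788-3p 123 ± 13.6). V254I (0.292% ± 0.0799) and H751L (0.255% ± 0.0679) lay near WT, and the null IP libraries held 0.635% and 0.258%. In total RNA the shares were 0.448% ± 0.0803 in WT, 1.46% ± 0.266 in F180del, 1.29% ± 0.101 in G199S, 1.16% ± 0.204 in null, 0.753% ± 0.137 in H751L and 0.373% ± 0.0240 in V254I. In F180del and G199S both IP libraries lay above both WT IP libraries, the most that 2 against 2 can show (smallest exact permutation p 0.333).

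Hairpin by hairpin, the passenger to guide ratio in the F180del IP rose in 38 of 83 hairpins and fell in 2, with a median log2 change of 2.26 (limma). The miR-72 passenger went from 0.148% ± 0.0268 of its guide in WT to 28.6% ± 4.98 (7.60 ± 0.65 on the log2 scale, adjusted p = 4.05e-05), and the miR-87 passenger from 0.0103% ± 0.00382 to 5.27% ± 0.733. In the G199S IP 30 rose and 1 fell, with a median of 1.66, and the miR-44 passenger went from 0.152% ± 0.0300 to 25.5% ± 1.39 of its guide. In the mir-75 hairpin the passenger was at 117% ± 9.58 of its guide in the WT IP and at 13.8% ± 5.23 in F180del (-3.14 ± 0.86). H751L had 1 higher hairpin in IP (miR-51), V254I had 0 by limma (0 at an unadjusted p under 0.05), and the null had 11 higher and 6 lower. In total RNA 12 hairpins rose in F180del, 13 in G199S, 5 in H751L (among them miR-235 and miR-240) and 12 in null, where 1 fell. In the mir-236 hairpin the passenger was at 272% ± 197 of its guide in F180del total RNA and at 141% ± 37.1 in G199S total RNA. In WT total RNA it was at 1.39%. The arm called passenger there thus exceeded the guide on average in both alleles. As a set, passengers passed camera in the IP of F180del and G199S, also with an estimated correlation (adjusted p = 0.00598 and 0.0394); 47 of 104 rose and none fell in F180del, and 38 rose and 2 fell in G199S (47, 39 and 2 adjusted over the list alone). In total RNA the set passed in F180del, G199S, H751L and null (21, 18, 5 and 18 of 115 higher; 23, 24, 12 and 21 adjusted over the list alone), with adjusted p = 0.264, 0.515, 0.737 and 0.131 with an estimated correlation. Passengers were 47 of 61 higher calls in the F180del IP, against 104 of 250 tested with both arms named (Fisher's exact test, adjusted p = 7.87e-09), and 18 of 21 in null total. In IP the hairpins numbered 17 to 25 in F180del and 14 to 18 in G199S without any 1 library, and in null 52 without null library 2, 2 without WT library 1 and 1 without WT library 2. In total RNA they numbered 5 in F180del without its library 2 or WT library 1, 3 to 5 in G199S without either of its libraries or WT library 1, 0 to 1 in H751L without either of its libraries or WT library 1, 8 in H751L without WT library 2, and 0 in null without null library 2 and 6 without WT library 1.

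**Figure D4:**
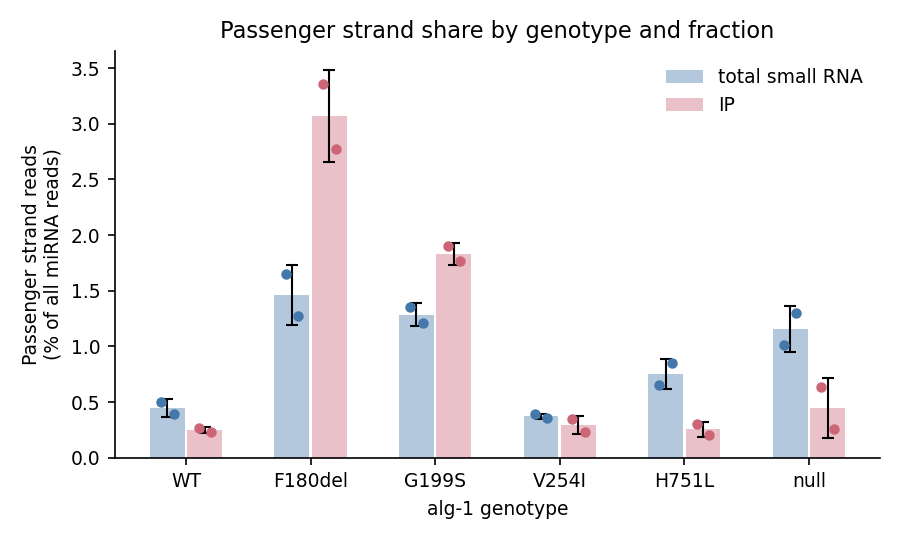
Passenger strand reads as a percentage of all miRNA reads by genotype, in total RNA (blue) and IP (red); bars are means of 2 libraries, points the libraries and error bars the SD. F180del and G199S reach 3.07% and 1.83% in IP against 0.252% in WT.

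In WT, 29 miRNAs were higher in IP than in total RNA and 40 lower, of 315. Enriched were miR-797-5p (5.73 ± 0.90), miR-57-5p (from 1114 ± 12.5 to 21539 ± 7242 RPM), miR-80-3p, miR-84-5p, miR-73-3p, miR-228-5p (2.22 ± 0.65) and miR-243-3p (from 54.6 ± 10.6 to 221 ± 49.5 RPM). Some of these varied widely between total libraries of one genotype. miR-80-3p was at 29763 and 2767 RPM in null total RNA and miR-84-5p at 3054 and 20070 RPM in F180del total RNA. The size of their enrichment in WT thus depends on the WT total libraries. Depleted were miR-229-3p (from 5444 ± 536 to 66.9 ± 12.1 RPM), miR-789-3p, miR-61-5p and miR-42-3p (-2.27 ± 0.42). The calls split 26 higher to 66 lower with RLE factors and 22 to 69 with library totals, and numbered 28 without either WT IP library, 35 without WT total library 1, 113 with only the compared groups and 107 with DESeq2. The direction of the split rested on single libraries: it was 18 higher to 10 lower without WT IP library 1, 21 to 7 without WT IP library 2, 31 to 26 without WT total library 2 and 7 to 28 without WT total library 1.

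Whether an allele changed the association given the level in total RNA was tested by the interaction. In F180del the IP to total ratio was higher than in WT for 4 miRNAs and lower for 3. Higher were miR-229-3p (4.73 ± 0.95, edgeR adjusted p = 0.00958) and the passengers miR-87-5p, miR-72-3p and miR-790-3p, the last chosen after its values were seen. Lower were miR-797-5p (-5.36 ± 1.10), miR-795-5p and miR-1820-5p. In IP these were at 82.6 ± 14.2, 441 ± 111 and 264 ± 182 RPM, against 277 ± 129, 329 ± 51.8 and 312 ± 44.9 RPM in WT. In total RNA they were at 49.1 ± 39.3, 201 ± 17.3 and 349 ± 431 RPM, against 7.37 ± 0.373, 10.4 ± 6.38 and 13.0 ± 5.19 RPM. The lower ratio of miR-795-5p thus went with a higher total level, not a lower IP level. miR-229-3p had more reads than miR-229-5p in total RNA but was the minor arm in the WT IP, at 66.9 ± 12.1 against 543 ± 72.5 RPM. In G199S the IP to total ratio was higher for the passengers miR-790-3p, miR-51-3p and miR-250-5p (3.65 ± 0.76, edgeR adjusted p = 0.0272). In null the ratio was higher for miR-51-3p and lower for miR-8200-3p, miR-788-3p and miR-79-5p. With the replicate block the calls numbered 0 in F180del, 0 in G199S and 2 in null. V254I and H751L had 0 by edgeR, with 5 and 27 at an unadjusted p under 0.05, and 0 and 3 by DESeq2. The calls in F180del fell to 0 without any 1 of F180del total library 2, F180del IP library 1, WT total library 1 or WT IP library 1, to 1 without F180del IP library 2, 2 without WT IP library 2 and 4 without WT total library 2; those in G199S fell to 0 without any library except WT total library 2, which left 2. In null 73 were called without null IP library 2, 7 without WT total library 2, and 1 without null total library 2 or WT total library 1. The G199S split was 4 higher and 3 lower with RLE factors and 11 to 16 with only the compared groups, and the null split 2 to 3 with RLE factors and 0 to 3 with library totals.

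Against the null in total RNA, F180del differed in 10 miRNAs (7 higher), G199S in 26 (23 higher), V254I in 35 (14 higher) and H751L in 10 (7 higher). miR-799, miR-788-5p and miR-255-3p were higher than in null in F180del, V254I and H751L, miR-799 by 5.37 ± 0.86, 4.77 ± 0.83 and 4.81 ± 0.84. They were not among the 8 named as higher in G199S, which does not show that G199S resembled null in them. There miR-255-3p was at 65.4 and 94.5 RPM, against 8.76 and 11.4 RPM in null. In G199S the 8 highest by the naming rule came from hairpins of the miR-35 family, led by the passenger miR-39-5p (6.07 ± 1.02, adjusted p = 0.000981) and miR-35-3p (5.32 ± 0.61, adjusted p = 8.12e-05). In V254I the passengers miR-79-5p, let-7-3p and miR-82-5p were lower than in null, miR-79-5p by 4.84 ± 0.76 in log2 size. The F180del split was 25 higher to 2 lower with library totals and the H751L split 7 to 5. V254I fell to 3 without its library 1 (3 higher, 0 lower), 7 without its library 2 (5 to 2) and 12 without null library 2, F180del to 3 without null library 1, H751L to 4 without null library 1 or its own library 1, and G199S to 13 without null library 2 and 16 without its own library 1. F180del rose to 19 and 17 without its library 1 and 2. DESeq2 called 53, 77, 57 and 47 in the 4 comparisons, and H751L had 0 with only the compared groups.

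Log2 changes against WT in total RNA correlated across 303 miRNAs with those of null at r = 0.58 in F180del, 0.45 in G199S, 0.29 in V254I and 0.52 in H751L. Shared WT libraries alone gave r = 0.52 on average in simulated unchanged groups. The covariances were 2.92, 2.54, 0.88 and 2.24, against 0.63 simulated. Over the 183 miRNAs with a mean of at least 10 RPM they were 1.79, 1.75, 0.26 and 0.98, against 0.31 simulated. That of V254I then did not exceed the simulated value. In IP (269 miRNAs) r was 0.27, 0.34, 0.10 and 0.38 against 0.47 simulated, and the covariances 2.03, 2.53, 0.29 and 1.97 against 0.40. The controls were not split, since each comparison would keep 1 WT library, so part of these values may come from the shared WT libraries. F180del and null shared 14 higher calls in total RNA, where independent lists would share 2.58. F180del and G199S shared 21 in total RNA (3.70 for independent lists) and 45 in IP (13.1). Simulated unchanged groups had 0.04 calls on average in total RNA and 0.02 in IP and shared 0, too few to set against these lists. Their top-ranked higher miRNAs, as many as the observed lists held, shared 11.7 on average (at most 16 in 100 draws) for F180del and null, so the 14 lay within that range. For F180del and G199S these shared 14.6 (at most 20) in total RNA and 29.9 (at most 36) in IP.

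Among the 4 NDD alleles 52 miRNAs differed in total RNA and 100 in IP by the edgeR F-test. miR-35-3p led both (adjusted p = 1.16e-05 and 4.85e-07). In IP it was at 31832 ± 221 RPM in G199S, 3541 ± 508 RPM in F180del, 1768 ± 21.8 RPM in V254I and 1074 ± 10.8 RPM in H751L. miR-72-3p, a passenger, was at 2458 ± 400 RPM in F180del, 524 ± 124 RPM in G199S, 10.5 ± 2.24 RPM in V254I and 16.5 ± 6.67 RPM in H751L. DESeq2 called 93 in total RNA, and 153 were called in IP with only the 4 alleles in the fit.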

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

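Of the tests in this part, that of library depth was set before its result was seen, and those of lysate carry-over, shared reads, scaling and embryo content after the results they concern. Differences between the 4 NDD alleles were picked out by the F-test among them (edgeR adjusted p, mean of at least 10 RPM, the 3 lowest per fraction). In total RNA these were miR-35-3p (1.16e-05), miR-39-3p (5.39e-05) and miR-37-3p (5.39e-05), each highest in G199S. In IP they were miR-35-3p (4.85e-07), miR-40-3p (3.07e-06), both highest in G199S, and miR-72-3p (3.64e-06), highest in F180del.

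Passenger strands gained in the F180del and G199S IP. Lysate RNA carried into the precipitate would hold the share at or below that of total RNA, but the lowest IP library exceeded the highest total library by 1.13 percentage points in F180del and 0.407 in G199S. After thinning each IP library to 3940626 reads the median log2 change of the ratio was 2.31 in F180del and 1.94 in G199S over 72 hairpins. Thinning lowers both arms of a hairpin alike. It therefore checks only effects of depth through the pseudocount and the count minimum, and cannot decide on depth otherwise. A candidate explanation is that these proteins keep duplexes from which the passenger is normally removed, a hypothesis found on the same libraries and not tested by an independent measurement. A change in which arm is chosen as guide stays open as well.

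The miR-35 to miR-41 rise in G199S. Reads moving between family members would leave their sum in place, but the 8 members together rose 6.15-fold in RPM, with no overlap of libraries; reads counted for several members at once would raise the sum and were not separated. The TMM factors are argued against as the cause, since the median log2 change of the 7 members was 4.63 in RPM, which uses library totals. miR-42-3p, the eighth member, changed by -0.36 ± 0.51 on the log2 scale in total RNA and 0.41 ± 0.32 in IP (SE, TMM). With library totals, the scale of RPM, it changed by -0.17 ± 0.47 and 0.70 ± 0.34. A gain equal to the median of the other 7 (11318 RPM in total, 3756 RPM in IP) would have given 0.91 and 1.61, which lie 2.28 and 2.71 SE higher. The gains of the 7 ran from 154 to 43437 RPM in total RNA, though, and how much miR-42-3p embryos or oocytes hold is not known from these libraries. More embryos or oocytes in the animals at harvest thus cannot be told apart from a rise per cell.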

How the results depend on the processing

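The alternatives were planned before the data were examined, except the passenger share over hairpins whose guide has at least 10 times the passenger's reads, and the block for shares and correlations, which were chosen after seeing the data. Of 2575 values recomputed for 229 named changes, 2062 kept their direction and side of the threshold, 507 fell short of it, 4 newly passed it and 2 changed sign. Those were the total RNA changes in null of let-7-5p, 0.71 on the log2 scale but -0.86 without null library 1 (-0.86 to 1.12 with any 1 library left out), and of miR-124-3p, 0.88 but -1.45 without null library 2 (-1.45 to 1.69); neither passed the threshold. Among the counts, medians, folds and correlations that answer a comparison, 316 recomputed values stayed within their limit (1.5 times for counts, the spread of libraries otherwise) and 180 did not; the latter are given below, with left-out libraries as ranges. The cause was not tested for any value below unless a sentence names it. Depth limits low miRNAs, since a count of 0 allows up to 0.761 RPM in the shallowest library.

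With only the compared groups in the fit, called miRNAs numbered 25 in F180del total, 82 in G199S total, 0 in H751L total, 11 in null total, 138 in F180del IP, 26 in H751L IP, 18 in null IP, 113 in WT IP to total, 11 in the interaction of F180del, 27 in the interaction of G199S, 1 in the interaction of null, 46 in G199S to null, 20 in V254I to null, 0 in H751L to null, 153 in the 4 alleles in IP. DESeq2 called 80 in F180del total, 74 in G199S total, 19 in H751L total, 67 in null total, 21 in H751L IP, 107 in WT IP to total, 16 in the interaction of F180del, 13 in the interaction of G199S, 3 in the interaction of H751L, 19 in the interaction of null, 53 in F180del to null, 77 in G199S to null, 57 in V254I to null, 47 in H751L to null, 93 in the 4 alleles in total. It gave no adjusted p for 67 miRNAs in the interaction of F180del. Without the filter the counts were 62 in G199S total, 1 in V254I total, 14 in H751L total, 13 in H751L IP, 9 in the interaction of G199S, 22 in F180del to null, 45 in G199S to null, 24 in H751L to null. All precursor rows gave 1 in H751L total, 32 in F180del to null, RLE factors 7 in the interaction of G199S, 24 in F180del to null, and library totals 27 in F180del to null. Without 1 library at a time the counts ran from 1 to 49 in F180del total, 12 to 21 in G199S total, 0 to 1 in H751L total, 3 to 18 in null total, 39 to 62 in F180del IP, 31 to 48 in G199S IP, 2 to 3 in H751L IP, 62 to 168 in null IP, 28 to 57 in WT IP to total, 0 to 6 in interaction of F180del, 0 to 2 in interaction of G199S, 1 to 73 in interaction of null, 3 to 19 in F180del to null, 13 to 29 in G199S to null, 3 to 27 in V254I to null, 4 to 10 in H751L to null. A lone library left in a group is assumed there to vary like the other groups.

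Hairpins with a changed ratio numbered 19 in F180del total with a minimum of 50 passenger reads, where fewer were tested, and 3 in H751L total, 5 in H751L IP, 32 in null IP with a pseudocount of 5. The median ratio change with that pseudocount was 1.12 in F180del total, 0.50 in G199S total, 0.27 in H751L total, 2.10 in F180del IP, -0.31 in H751L IP. With the minimum of 50 it was 1.66 in F180del total, 1.09 in G199S total, 1.83 in G199S IP, and with guides set from WT 0.94 in G199S total, 1.83 in G199S IP, -0.34 in H751L IP. Without 1 library at a time hairpins ran from 5 to 12 in F180del total, 3 to 17 in G199S total, 0 to 8 in H751L total, 0 to 12 in null total, 17 to 25 in F180del IP, 14 to 18 in G199S IP, 0 to 1 in H751L IP, 1 to 52 in null IP. The medians ran from 0.98 to 1.58 in F180del total, 0.65 to 0.88 in G199S total, -0.34 to 0.0372 in V254I total, 0.22 to 0.64 in H751L total, 0.97 to 1.77 in null total, 1.94 to 2.20 in F180del IP, -0.12 to 0.0338 in V254I IP, -0.33 to -0.22 in H751L IP. The fold of the passenger share was 3.34 in null total, 14.5 in F180del IP, 8.17 in G199S IP over hairpins with a clear guide.

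Lists past camera numbered 0 in F180del total, 0 in G199S total, 0 in H751L total, 0 in null total, 1 in G199S IP, 0 in V254I IP, 0 in null IP with an estimated correlation, and 0 in V254I IP, 1 in null IP with library totals. The correlation with null over miRNAs with a mean of at least 10 RPM was 0.17 in V254I total, 0.45 in G199S IP, -0.20 in V254I IP.

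Replicate numbers did not pair the libraries throughout. Same-numbered libraries deviated together (r over 0.1) in 8 of 15 pairs in total RNA and 9 of 15 in IP. Total deviated with IP of one genotype in 2 of 6. The r ran from -0.32 to 0.61, -0.10 to 0.50 and -0.10 to 0.30. In total RNA it was 0.61 for V254I with H751L, 0.60 for H751L with null and 0.47 for V254I with null. F180del went against each of these (-0.29 to -0.32). In IP it was 0.50 for F180del with G199S and 0.41 for G199S with WT. A batch shared by some of the groups was thus not excluded. With the replicate block, called miRNAs numbered 13 in H751L total, 0 in the interaction of F180del, 0 in the interaction of G199S, 2 in the interaction of null, 16 in F180del to null, and hairpins 26 in F180del total, 8 in H751L total, 3 in H751L IP. Other counts of calls stayed within 1.5 times, and the counts of lists were unchanged. With the same block the fold of the passenger share was 12.1 in F180del IP and 7.29 in G199S IP, and no share moved by more than the spread of its libraries and no correlation with null by 0.1.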

Other observations

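The test of lysate carry-over in the null IP was set before its result was seen; the correlations in single libraries and in other genotypes were chosen after it.

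Some total libraries of one genotype lay far apart. miR-48-5p, a larval timing miRNA of the let-7 family, was at 121743 and 24629 RPM in the null total libraries and at 78129 and 17738 RPM in those of H751L, against 42036 and 60018 RPM in WT. In IP the same miRNA was at 154241 and 125466 RPM in null and at 70984 and 58668 RPM in H751L. The standard deviation over miRNAs of the log2 difference between the libraries of a group was 1.41 in null, 1.36 in H751L, 1.18 in F180del, 1.00 in V254I, 0.83 in WT and 0.66 in G199S in total RNA. In IP it was 1.42 in null, 0.78 in H751L, 0.67 in G199S, 0.61 in F180del, 0.58 in WT and 0.46 in V254I.

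miR-8200-3p differed widely between genotypes. It was at 56.9 ± 6.26 RPM in WT total, 43.3 ± 8.88 in V254I, 18.9 ± 1.92 in F180del, 10.6 ± 4.29 in null, 4.61 ± 1.98 in H751L and 0.112 ± 0.0147 in G199S (SD, n = 2). In IP it was at 71.7 ± 8.93 RPM in WT, 79.2 ± 14.2 in V254I, 41.2 ± 1.25 in F180del, 1.21 ± 0.0253 in H751L and 0.131 ± 0.185 in G199S, with 0 reads in null. Its hairpin lies on chromosome V at 3057062 to 3057117 (WBcel235), outside protein-coding genes. miR-243-3p, known from RDE-1, was higher in the WT IP than in WT total RNA, and lower in the IP of G199S, H751L and null than in the WT IP.

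Over the 10 comparisons with WT, the remaining lists gave these calls. The lin-4 family had 0 higher and 2 lower, miR-51 had 1 and 4, miR-58 had 2 and 3, and miR-44 had 1 and 2. The miR-2 family had 1 and 2, miR-72 had 0 and 1, the miR-238 family had 0 and 0, and the other small seed families 3 and 3. Stress and lifespan miRNAs had 13 and 8, tissue-restricted miRNAs 0 and 6, and the RDE-1 associated miRNA 0 and 3. By the test adjusted over the list alone, lin-4 had 1 higher and 4 lower, miR-51 had 1 and 3, miR-44 had 1 and 8, miR-2 had 0 and 2, and miR-72 had 0 and 2. Stress and lifespan miRNAs had 15 and 12, tissue-restricted miRNAs 0 and 3, and the RDE-1 associated miRNA 0 and 4, with the other lists unchanged. The miR-44 list counts miR-44-3p and miR-45-3p apart, although their levels were nearly equal in every library.

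The null IP kept much of the WT pattern of enrichment. Over 108 guides the log2 ratio of IP to total in null correlated with that in WT at r = 0.854 (95% interval 0.794 to 0.898, across miRNAs, which are not independent), and at 0.775 and 0.904 with either null IP library alone. A low correlation was set beforehand as the mark of lysate RNA as the whole content. The test cannot exclude lysate RNA, because the 2 null total libraries themselves differed in miRNAs that the WT IP enriched. There miR-80-3p was at 29763 and 2767 RPM and miR-57-5p at 3007 and 709 RPM. A precipitate resembling null total library 1 could therefore also give a positive correlation. An open candidate explanation is that the precipitation also recovers another Argonaute; a bias shared by all IP libraries stays open too, since no library from a precipitation without antibody was analysed here. In the same measure r was 0.739 in F180del, 0.743 in G199S, 0.924 in V254I and 0.942 in H751L.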
